A study of Mus musculus with 15 samples.

How the data were processed

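RNA was measured by sequencing in the striatum of 15 mice aged 6 months, 1 library per mouse. The labels give genotype as the factor that differs between groups: 7 libraries are WT, 4 are E1 and 4 are KI-96. Per the labels' protocols, RNA was extracted from striatum with a column kit for lipid-rich tissue and the libraries were built by a sequencing provider. The kind of library, its strandedness, the read length and the sex of the animals are not given in the sources used here.

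The deposited table holds whole-number read counts per gene with 1 column per mouse, and the authors applied no normalization to these counts, as the different column totals show. The submitters' processing notes name STAR, HTSeq, the build GRCm38 and DESeq2 1.24.0, with no role, order or setting for any of them. The gene identifiers are versioned Ensembl mouse identifiers, and the annotation release used for counting is not given in the sources used here. Of 54232 identifiers in the table, 54165 matched a mouse annotation of build GRCm38 without their version and 52566 matched with it. Gene symbols, gene types and coordinates come from that annotation. Whether counting used strand is not given, so antisense and overlapping genes, pseudogenes and near-identical gene copies are reported as uncertain.

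Total counts per library ranged from 14678565 to 26388542. All 33 pairs of libraries within a group differed by more than sampling noise: the smallest chi-square per degree of freedom over genes was 8.59, and Spearman correlations lay between 0.965 and 0.993. Each library carries its own mouse number, so the replicates are separate animals.

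Genes were kept with the default filter of edgeR 4.0.16 by group (a minimum count of 10), which left 18278 genes. Counts were normalized with the trimmed mean of M-values. A quasi-likelihood model with robust estimation was fitted to all 15 libraries with group as the single factor, so that the 3 groups shared 1 estimate of the spread per gene. The 3 comparisons were contrasts of group means, tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes in the text are from this model unless another tool is named. Levels are given as CPM (counts scaled by library total) computed with the normalized library sizes, and log2 CPM used a prior count of 2. For Htt and Dusp5 an exact permutation test of log2 CPM was also run, two-sided. Across 330 splits of 4 against 7 libraries its smallest possible p is 0.00303, and across 70 splits of 4 against 4 it is 0.0286.

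In all, 34 gene lists were written before the data were examined. They cover striatal projection neurons and interneurons, the other cell types of the striatum and its neighbouring tissues, cell stress and protein clearance, immediate early genes, interferon response, DNA repair, transport, synapse, development, the neighbours of Htt, and sex-linked genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of 1 comparison. Camera asks whether a list ranks apart from all other genes. The same test was run with a correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in 1 direction. An exact permutation test of each list's mean log2 CPM per library was added after the data were seen. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

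The genes named for each comparison followed a rule written before the data were examined. Htt was always named. Also named were the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 1 CPM and a symbol that is not a predicted gene. From each list the 3 members with the smallest adjusted p under 0.05 were to be named. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values. Other genes in the text are examples from the lists or were chosen after their values were seen.

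The tests were run on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. For E1 against WT, over 18211 genes, edgeR recovered 34.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 3-fold. In that run 14 of 169 calls were false (8.28%). For KI-96 against WT, over 18218 genes, the recovered shares were 38.8%, 76.1% and 95.5%, with 6 of 165 calls false. For KI-96 against E1, over 18216 genes, they were 34.3%, 74.6% and 90.9%, with 6 of 154 calls false. The shares of false calls by DESeq2 in the 3 runs were 15.5%, 7.14% and 12.5%. Those of limma-voom were 7.78%, 3.19% and 2.84%. A proteasome list raised 1.5-fold was called by camera in each run, and 0 of the other 33 lists were called at an adjusted p under 0.05. Simulated genes were drawn independently of each other. These runs therefore cannot show how often camera calls unchanged lists where genes move together.

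Alternatives planned before the data were examined were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of a mean of at least 1 CPM, a fit of the 2 compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a covariate of summed Y-linked expression (4 genes), a fit without robust estimation, a minimum absolute log2 fold change of 0.5, and leaving out each library in turn. Alternatives added after the data were seen left out 3 libraries with high cortical markers, 1 library apart on the first principal component, or all 4, or used the cortical marker mean as a covariate. To judge the overlap of the E1 and KI-96 effects, which share the WT libraries, unchanged groups were simulated against those libraries and the WT libraries were split between the comparisons. All computation used R 4.3.3. No column of the table was left out.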

Results

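Striatal RNA was sequenced from mice aged 6 months of 3 genotypes, WT (n = 7), E1 (n = 4) and KI-96 (n = 4). The study's title concerns toxicity from RAN translation, the translation of expanded repeats without a start codon, in knock-in mice of Huntington's disease. The striatum is the brain region most affected in this disease, and knock-in mice carry an expanded CAG repeat in their own Htt gene. E1 and KI-96 are genotype names that the labels give without further description. Reads were counted per gene, and each library came from a separate mouse.

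Total counts per library ran from 17281603 to 26388542 in WT, from 18199927 to 19533231 in E1 and from 14678565 to 23373551 in KI-96. Mitochondrial genes took 5.33% ± 0.422 (SD, n = 7) of counts in WT, 5.47% ± 0.393 (n = 4) in E1 and 4.85% ± 1.14 (n = 4) in KI-96. On the first principal component, which held 18.3% of the variance, KI-96 replicate 3 lay at 73.0 and the other 14 libraries between -34.7 and 23.1. WT replicates 5, 6 and 7 had the highest totals of their group, from 23457270 to 26388542, and lay between 30.5 and 33.0 on the second component, which held 16.4%. The labels give no batch.

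Htt, which encodes huntingtin (chromosome 5, 34761740 to 34912534, build GRCm38), was measured in every library. Its level was 179 ± 10.0 CPM (SD, n = 7) in WT, 142 ± 5.66 (n = 4) in E1 and 187 ± 40.4 (n = 4) in KI-96. All 4 E1 libraries (135 to 148 CPM) lay below all 7 WT libraries (169 to 197 CPM). For E1 against WT the log2 fold change was -0.34 (SE 0.11), and the exact permutation p was 0.00303, the smallest that 330 splits can give. Adjusted over all genes tested, the edgeR adjusted p was 0.450, which did not pass the threshold. KI-96 differed from WT by a log2 fold change of 0.06 (SE 0.11, adjusted p = 0.862, exact permutation p = 0.697). The spread within KI-96 was wide, from 144 to 242 CPM, and without KI-96 replicate 3 that fold change was -0.08. Against E1, KI-96 had a log2 fold change of 0.40 (SE 0.12, adjusted p = 0.212, exact permutation p = 0.0857). Without KI-96 replicate 4 it was 0.51, with an adjusted p of 0.0443, and without KI-96 replicate 3 it was 0.25. The genes that neighbour Htt on chromosome 5 did not pass camera in any comparison: of 23 tested, 8 had positive fold changes in E1 against WT (median -0.06, adjusted p = 0.378), 11 in KI-96 against WT (median -0.02, adjusted p = 0.660) and 15 in KI-96 against E1 (median 0.03, adjusted p = 0.183).

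To ask whether either mutant striatum had lost the genes of its principal neurons, 35 genes of medium spiny projection neurons were compared. None of the 35 passed the edgeR threshold against WT in E1 or in KI-96, over all genes or adjusted over the list alone (smallest adjusted p over the list alone 0.871 and 0.827), while 1 of 35 in each had an unadjusted p under 0.05. Over all genes DESeq2 called 58 genes in E1 and 70 in KI-96, and limma-voom 2 and 0. In E1, log2 fold changes ran from -0.24 for Strip2 to 0.32 for Itpka, with a median of 0.10 and 24 of 35 positive. In KI-96 they ran from -0.67 for Pcp4, a calmodulin-binding protein, to 0.30 for Gnal, the G protein subunit that couples dopamine receptors to cyclase. The KI-96 median was 0.01, with 18 of 35 positive. Camera adjusted p-values of the list were 0.175 in E1 and 0.954 in KI-96. Drd1, the dopamine receptor of direct pathway neurons, had log2 fold changes of 0.12 (SE 0.15) in E1 and -0.16 (SE 0.15) in KI-96. Drd2, the receptor of indirect pathway neurons, had 0.12 (SE 0.17) and 0.09 (SE 0.17). Penk, which encodes enkephalin, had 0.16 (SE 0.22) and -0.38 (SE 0.22). Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, had 0.12 (SE 0.21) and -0.13 (SE 0.21), and Pde10a, a striatal phosphodiesterase, had -0.10 (SE 0.19) and -0.16 (SE 0.19). The 95% intervals lay above a log2 fold change of -1 for all 35 genes in E1 and for 34 of 35 in KI-96, where Pcp4 reached -1.67. The separate lists of direct and indirect pathway genes had camera adjusted p-values of 0.971 and 0.814 in E1, and of 0.977 and 0.991 in KI-96.

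**Figure D1:**
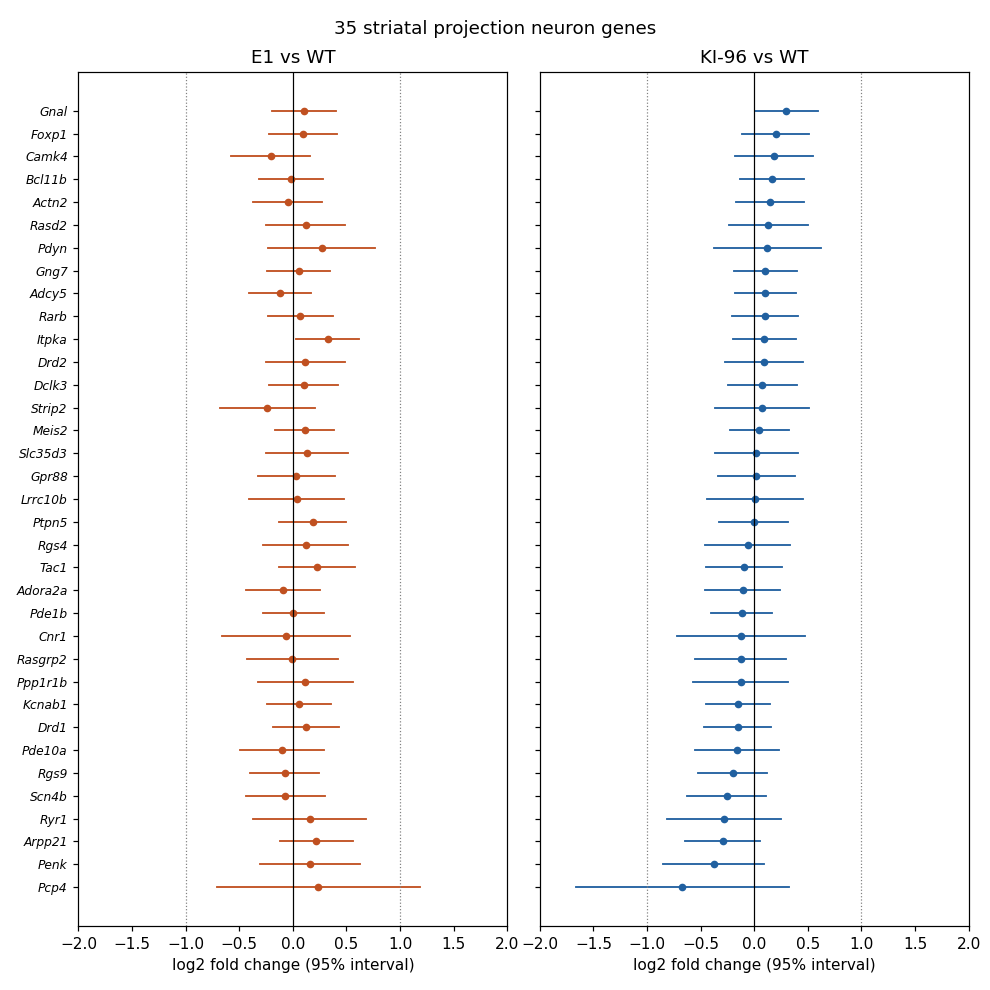
Log2 fold change against WT (horizontal axis) of 35 genes of striatal projection neurons in E1 and in KI-96, with 95% intervals from the edgeR model of 7 WT, 4 E1 and 4 KI-96 libraries. Values run from -0.24 to 0.32 in E1 and from -0.67 (Pcp4) to 0.30 in KI-96.

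To find genes that differed in E1 striatum, E1 was compared with WT. Dusp5 (chromosome 19, 53529109 to 53542431), a nuclear phosphatase of ERK kinases induced by ERK signalling, rose from 9.65 ± 0.751 CPM (SD, n = 7) in WT to 16.8 ± 2.74 (n = 4) in E1. Its log2 fold change was 0.80 (SE 0.11, edgeR adjusted p = 0.0339), all 4 E1 libraries lay above all 7 WT libraries, and KI-96 had 11.1 ± 1.15 CPM (n = 4). It was the single gene of 18278 past the threshold, and 0 genes passed in the other direction. At an unadjusted p under 0.05 there were 1599 genes, 674 higher and 925 lower, where 914 in all are expected on average by chance. Of 100 splits of these libraries into groups of the same sizes, the real one included, 7 gave at least 1599, with up to 2189. DESeq2 called 58 genes and limma-voom 2, Dusp5 and the X-linked Xist. The call of Dusp5 ended on leaving out any 1 of WT replicates 2 to 7, E1 replicates 1 to 3 or KI-96 replicates 2 and 4 (log2 fold change 0.68 to 0.86, adjusted p up to 0.160 over all libraries left out in turn). It also ended with no filter, with only E1 and WT in the fit, with the Y-linked covariate, with the cortical marker covariate (0.74), and without the 3 libraries with high cortical markers (0.63). The count rose to 257 genes without E1 replicate 4 and to 12 without WT replicate 1. Among the 12 were the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, and the X-linked Xist. Leaving out that library left a WT group in which every library held Y-linked reads.

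**Figure D2:**
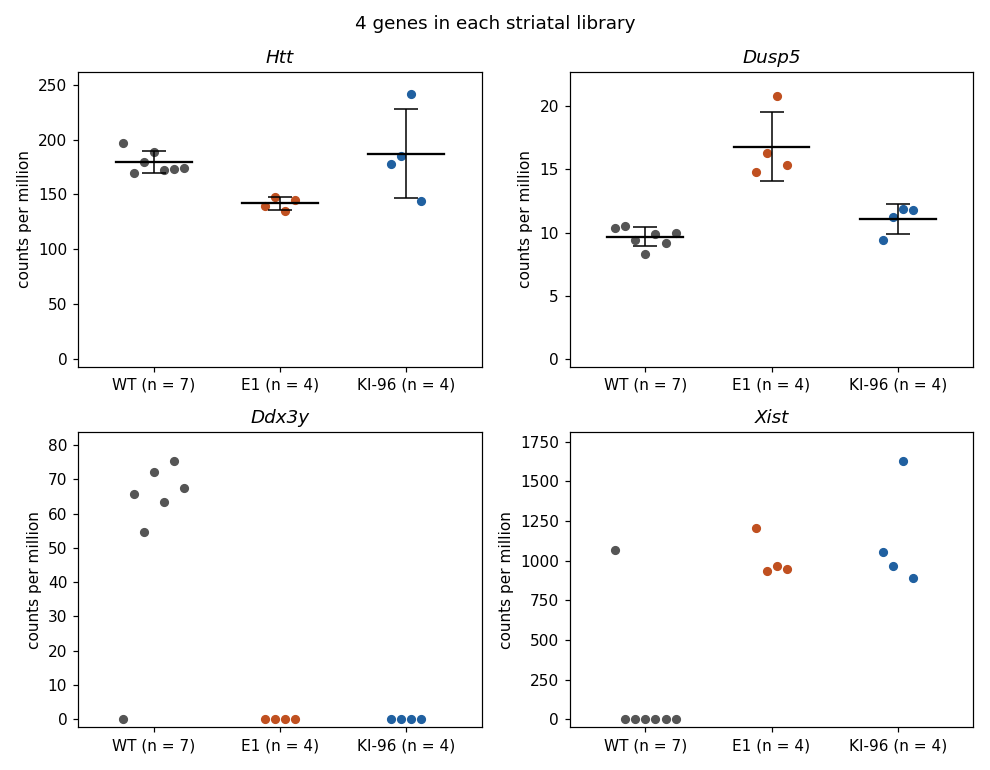
CPM (vertical axis) of Htt, Dusp5, Ddx3y and Xist in each library (points) of WT (n = 7), E1 (n = 4) and KI-96 (n = 4), with mean (line) and SD (bars) for Htt and Dusp5. E1 libraries hold 135 to 148 CPM of Htt and WT libraries 169 to 197, and 1 WT library has 0 counts of the Y-linked gene Ddx3y.

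Immediate early genes, which neurons switch on within minutes of activity, were higher in E1 than in WT. All 24 tested members had positive fold changes, with a median of 0.70. Of these 10 rose adjusted over the list alone, and over all genes tested 0 did. Among the 10 were the transcription factors Egr1 (log2 fold change 0.83, SE 0.20) and Fosb (1.16, SE 0.27), the ERK phosphatase Dusp6 (0.74, SE 0.17) and Arc, a regulator of synaptic receptors (0.70, SE 0.23). Egr1 stood at 479 ± 120 CPM (SD, n = 4) in E1 and 270 ± 56.3 (n = 7) in WT. The list's mean log2 CPM was 5.29 to 5.96 in the 4 E1 libraries and 4.44 to 5.29 in the 7 WT libraries. Camera gave an adjusted p of 3.06e-20, and the adjusted p = 0.0535 with an estimated correlation. The exact permutation p of the list mean was 0.00303, the smallest 330 splits can give, and 0.103 after adjustment over 34 lists. The call held on leaving out each library in turn.

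Interferon response genes, which cells raise on sensing viral or double-stranded RNA, were higher in E1 largely through 1 animal. Of 25 tested members 24 had positive fold changes (median 1.10), and adjusted over the list alone 17 rose, while 0 did over all genes. Irf7, a transcription factor that amplifies this response, had a log2 fold change of 2.33 (SE 0.57), and Ifit1, which binds foreign RNA, had 1.92 (SE 0.61). The list mean was 3.64 in E1 replicate 1, 1.17 to 1.81 in the other 3 E1 libraries and 1.16 to 1.51 in WT. Camera gave an adjusted p of 4.69e-12, with an adjusted p = 0.530 with an estimated correlation. Without E1 replicate 1 the median was 0.23, and the call held. The reactive astrocyte list (27 tested, 18 positive and 9 negative, median 0.13, adjusted p = 0.0387, adjusted p = 0.606 with an estimated correlation) had 3 members that rose adjusted over the list alone and 0 over all genes. These were the interferon-induced GTPases Iigp1 (2.34, SE 0.64) and Gbp2 (1.35, SE 0.42), and the glycosyltransferase B3gnt5 (1.10, SE 0.32). Gfap, another member, was lower in E1, at 111 ± 72.0 CPM (SD, n = 4) against 179 ± 45.8 (n = 7) in WT. Without E1 replicate 1 the median of the reactive astrocyte list was -0.02 and its call ended, as it did without WT replicate 3 (0.12), 5 (0.06) or 7 (0.11). The median was 0.21 without WT replicate 1, and 0.25, 0.23 and 0.22 without E1 replicates 2, 3 and 4.

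Genes of myelin and mature oligodendrocytes, the cells that insulate axons, were lower in E1. All 23 had negative fold changes (median -0.36, camera adjusted p = 4.1e-10, adjusted p = 0.565 with an estimated correlation), and 0 fell adjusted over the list alone or over all genes. Mbp, which encodes myelin basic protein, had a log2 fold change of -0.38 (SE 0.22), and Mog, a glycoprotein of the outer myelin surface, had -0.38 (SE 0.21). Libraries of this group differed widely: the list mean was 6.31 in E1 replicate 3 and 7.66 in E1 replicate 4, and 6.95 to 7.50 in WT. The median was -0.19 without E1 replicate 3 and -0.76 without E1 replicate 4. Homeostatic astrocyte markers were also lower (14 of 17 negative, median -0.22, adjusted p = 0.000565, adjusted p = 0.530 with an estimated correlation). Of its members 2 fell adjusted over the list alone, the potassium channel Kcnj10 (-0.64, SE 0.15) and the bicarbonate transporter Slc4a4 (-0.36, SE 0.10), and 0 did over all genes. That median was -0.12 without E1 replicate 1, -0.11 without E1 replicate 2 and -0.37 without E1 replicate 4.

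Markers of tissue next to the striatum moved with some of the same libraries. Cortical excitatory neuron markers had a mean log2 CPM of 5.93 in WT replicate 3, 6.05 in E1 replicate 2 and 5.39 in E1 replicate 3, and 2.65 to 3.82 in the other 12 libraries. Slc17a7, the glutamate transporter of cortical neurons, reached 816 CPM in WT and 914 CPM in E1. In E1 against WT 14 of the 15 cortical markers were positive (median 1.00, camera adjusted p = 0.00783, adjusted p = 0.606 with an estimated correlation) and 0 rose adjusted over the list alone. That median was 0.15 without E1 replicate 2, which ended the call, as did leaving out E1 replicate 3 (0.87). It was 1.82 without WT replicate 3. Without all 3 of these libraries the myelin median was -0.00 and its call ended, and immediate early genes kept their call with a median of 0.55. Choroid plexus markers (1 of 15 positive, median -0.55, adjusted p = 0.00222, adjusted p = 0.606 with an estimated correlation) lost their call without WT replicate 2 (-0.21) or E1 replicate 2 (-0.36). Blood markers (6 of 7 positive, median 0.76, adjusted p = 0.000467, adjusted p = 0.488 with an estimated correlation) had 3 members that rose adjusted over the list alone, among them the globins Hbb-bt and Hba-a2 (1.38, SE 0.51), and over all genes 0 did. That call ended without E1 replicate 2 (0.36).

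Another 6 lists passed camera in E1 against WT, and each lost its call with an estimated correlation. Proteasome genes (23 of 25 positive, median 0.13, adjusted p = 0.000467, adjusted p = 0.606 with an estimated correlation) had an exact permutation p of 0.00909 for the list mean, 0.137 after adjustment. Endoplasmic reticulum stress genes (18 of 21 positive, median 0.18, adjusted p = 0.00150, adjusted p = 0.606 with an estimated correlation) lost their call without E1 replicate 3 (0.15). Genes of the p53 response (15 of 17 positive, median 0.15, adjusted p = 0.0165, adjusted p = 0.488 with an estimated correlation) lost it without WT replicate 1 (0.14) or E1 replicate 2 (0.12). Striatal interneuron markers were lower (11 of 15 negative, median -0.16, adjusted p = 0.0252, adjusted p = 0.606 with an estimated correlation). Chat, the acetylcholine-synthesizing enzyme of cholinergic interneurons (-0.48, SE 0.14), and the substance P receptor Tacr1 (-0.34, SE 0.10) fell adjusted over the list alone, and 0 members did over all genes. The interneuron call ended without WT replicate 1 (-0.12), E1 replicate 1 (-0.10) or E1 replicate 2 (-0.10). Markers of thalamus, pallidum and habenula (2 of 13 positive, median -0.33, adjusted p = 0.0382, adjusted p = 0.606 with an estimated correlation) lost their call without any 1 of WT replicates 1, 3, 5 or 7 or E1 replicates 1, 2 or 3 (medians of -0.21 to -0.40). Ependymal markers (12 of 13 positive, median 0.30, adjusted p = 0.0382, adjusted p = 0.748 with an estimated correlation) lost it without any 1 of WT replicates 1, 3 or 4 or E1 replicates 1, 3 or 4 (medians of 0.12 to 0.32), and had a median of 0.49 without E1 replicate 2.

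The remaining lists did not pass camera in E1 against WT. Their medians and adjusted p-values were 0.01 and 0.551 for homeostatic microglia, -0.00 and 0.766 for activated microglia, -0.17 and 0.0957 for oligodendrocyte precursors, 0.02 and 0.427 for cholesterol synthesis, and 0.08 and 0.132 for cytosolic chaperones. They were 0.06 and 0.135 for the respiratory chain, 0.06 and 0.902 for autophagy and lysosome, -0.07 and 0.130 for mismatch repair and repeat instability, 0.00 and 0.814 for nucleocytoplasmic transport, and 0.12 and 0.158 for the excitatory postsynapse. They were -0.16 and 0.708 for the 10 of 22 silenced developmental regulators with enough counts to be tested. They were 0.01 and 0.518 for clustered protocadherins, -0.23 and 0.0678 for septum and hypothalamus, 0.04 and 0.378 for endothelium and pericytes, and -0.02 and 0.766 for meningeal fibroblasts. Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell adjusted over the list alone (-0.43, SE 0.13), the developmental genes Dlx1 (0.56, SE 0.15) and Islr2 (0.88, SE 0.27) rose, and over all genes 0 of these did.

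Other settings moved several of these lists in E1 against WT. With the Y-linked covariate, where WT replicate 1 is the single WT library without Y-linked reads, the calls of choroid plexus (median -0.01), endoplasmic reticulum stress (0.01), reactive astrocyte (0.05) and interneuron (-0.20) lists ended. The medians of p53 response (0.26), ependymal (0.54), blood (1.31) and cortical (1.82) lists were further from 0. Without the 3 libraries with high cortical markers the calls of endoplasmic reticulum stress (0.08), p53 response (0.07), thalamus (-0.31) and choroid plexus (-0.37) lists ended, and cortical markers turned to -0.21. Interneuron (-0.27), reactive astrocyte (0.26), interferon (1.99) and ependymal (0.48) lists moved further from 0. That setting left 2 E1 libraries, among them E1 replicate 1 with the interferon list mean of 3.64, which then weighed more. With the cortical marker covariate homeostatic astrocyte (-0.13), reactive astrocyte (0.19) and myelin (-0.23) lists kept their calls and cortical markers lost theirs (-0.02). With 1 surrogate variable the reactive astrocyte call ended (0.13).

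Several further genes had the smallest p-values for E1 against WT without passing the threshold. Among those higher were Igf2bp2, an RNA-binding protein (chromosome 16, 22059009 to 22163299, log2 fold change 0.96, SE 0.20, adjusted p = 0.383), and Clmp, an adhesion molecule (chromosome 9, 40685962 to 40785319, 0.83, SE 0.17). Midn, which brings nuclear proteins to the proteasome, had 0.55 (SE 0.12, chromosome 10, 80148272 to 80158368). Dpysl5, a neurite growth protein, had 0.48 (SE 0.11, chromosome 5, 30711564 to 30799375), each with an adjusted p of 0.383. Among those lower were the antisense gene 1700034H15Rik (chromosome 1, 191886130 to 191907527, -1.01, SE 0.19, adjusted p = 0.294) and Catspere2 (chromosome 1, 177983423 to 178172704, -1.58, SE 0.33, adjusted p = 0.383). Both are uncertain, because the strand setting is not given in the sources used here and close copies share reads. The neighbouring pseudogene Catspere1 (chromosome 1, 177808550 to 177962233) had 73 to 240 counts in WT replicates 2 to 7, 1 in WT replicate 1, 0 or 1 in E1 libraries and 0 in KI-96 libraries. 1700034H15Rik was also low in WT replicate 1, the WT library without Y-linked reads, at 3.65 CPM against 5.83 to 6.66 in WT replicates 2 to 7. It was at 2.61 to 3.20 in E1 and 2.76 to 4.48 in KI-96. On leaving out WT replicate 1, edgeR called both 1700034H15Rik and Catspere2.

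Sex-linked transcripts differed between the genotypes. Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260771 to 1286629), had 931 to 2112 counts in WT replicates 2 to 7, 0 in WT replicate 1, 0 or 1 in E1 and 0 in KI-96. Kdm5d, a Y-linked histone demethylase (chromosome Y, 897788 to 956786), had 663 to 1346 counts in WT replicates 2 to 7 and at most 2 in the other 9 libraries. Xist, the RNA that silences 1 X chromosome in females, had 18403 counts in WT replicate 1, 5 to 51 in WT replicates 2 to 7, 16616 to 23494 in E1 and 14467 to 29782 in KI-96. The list of 5 tested sex-linked genes passed camera against WT in E1 (adjusted p = 3.74e-07, adjusted p = 0.0363 with an estimated correlation) and in KI-96 (adjusted p = 5.66e-06, adjusted p = 0.0566 with an estimated correlation), with 4 of 5 lower adjusted over the list alone in both. It did not in KI-96 against E1 (adjusted p = 0.995). In comparisons with WT, genotype therefore went with Y-linked expression in all libraries but WT replicate 1, whereas both mutant groups lacked it. With Y-linked expression as a covariate edgeR called 0 genes in either comparison with WT, with 454 genes at an unadjusted p under 0.05 for E1 and 218 for KI-96.

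To ask the same of KI-96 striatum, KI-96 was compared with WT. Tmem181b-ps, a transcribed pseudogene (chromosome 17, 6438524 to 6467022), had the smallest p, with 124 ± 33.6 CPM (SD, n = 4) in KI-96, 243 ± 41.4 (n = 7) in WT and 208 ± 24.3 (n = 4) in E1 (log2 fold change -0.97, SE 0.16, adjusted p = 0.236). It is uncertain because its reads can be shared with close copies. Coq10b, a coenzyme Q binding protein of mitochondria (chromosome 1, 55052770 to 55072702), had 12.2 ± 1.37 CPM (n = 4) in KI-96 and 17.8 ± 1.70 (n = 7) in WT (-0.55, SE 0.11, adjusted p = 0.241). Mfn2, a protein of mitochondrial fusion (chromosome 4, 147873599 to 147904704), had 267 ± 34.3 CPM (n = 4) and 190 ± 22.3 (n = 7), with a log2 fold change of 0.49 (SE 0.10, adjusted p = 0.241). EdgeR called 0 of 18278 genes (smallest adjusted p 0.236), with 1060 genes higher and 856 lower at an unadjusted p under 0.05. DESeq2 called 70 genes and limma-voom 0. Without WT replicate 1 the count was 11 genes, among them the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty, and the X-linked Xist. It was 2 without KI-96 replicate 3, Tmem181b-ps and the liver gene Alb, and 2 without KI-96 replicate 4.

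The other genes with the smallest p-values in KI-96 against WT had an adjusted p of 0.241. Eif2s3x, an X-linked translation factor that escapes X inactivation (chromosome X, 94188707 to 94212862), had a log2 fold change of 0.87 (SE 0.18). The long noncoding RNA Gm9866 (chromosome 12, 27050950 to 27160633) had 0.69 (SE 0.15). The pseudogenes Gm6477 (chromosome 10, 39198538 to 39199301) and Gm19196 (chromosome 12, 21543307 to 21554521) had 1.44 (SE 0.29) and 1.36 (SE 0.29). Among those lower were the small RNA Gm27544 (chromosome 10, 92071661 to 92071815, -2.54, SE 0.47) and the pseudogene Gm10180 (chromosome 9, 25101404 to 25101481, -2.22, SE 0.47). Pseudogenes are uncertain for the reason given above.

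Besides the sex-linked genes, groups that passed camera in KI-96 against WT included those of the ventricle wall and clustered protocadherins. All 13 ependymal and cilia markers, genes of the cells that line the ventricles, had negative fold changes (median -0.72, camera adjusted p = 7.81e-06, adjusted p = 0.908 with an estimated correlation). Fam183b and Tekt4, both genes of motile cilia, had -1.09 (SE 0.40) and -0.93 (SE 0.36). Choroid plexus markers were lower in 14 of 15 (median -0.81, adjusted p = 0.000369, adjusted p = 0.908 with an estimated correlation), and the median was -0.36 without WT replicate 2. All 21 clustered protocadherins of the beta group, neuronal adhesion genes with near-identical copies, had positive fold changes (median 0.30, adjusted p = 5.66e-06, adjusted p = 0.908 with an estimated correlation). Pcdhb22 had 0.41 (SE 0.14) and Pcdhb11 0.48 (SE 0.17), both uncertain as close copies. In these 3 lists edgeR called 0 members over all genes and 0 adjusted over the list alone, and limma-voom called 0 genes and DESeq2 70 over all genes. Unadjusted p-values were under 0.05 for 2 of 13 ependymal, 2 of 15 choroid plexus and 4 of 21 protocadherin genes.

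Cholesterol synthesis genes were lower in KI-96 than in WT (21 of 24 negative, median -0.19, adjusted p = 0.000369, adjusted p = 0.908 with an estimated correlation). There were 3 that fell adjusted over the list alone, and 0 over all genes: Idi1 (-0.56, SE 0.13), an isomerase of the isoprenoid steps, and the sterol demethylation enzymes Cyp51 (-0.32, SE 0.08) and Msmo1 (-0.36, SE 0.12). The median was -0.13 without WT replicate 3 and turned to 0.06 with the Y-linked covariate. Interferon response genes were positive in 22 of 25 (median 0.48, adjusted p = 0.00166, adjusted p = 0.941 with an estimated correlation), with 0.29 and no call without KI-96 replicate 4. Markers of thalamus, pallidum and habenula were positive in 12 of 13 (median 0.45, adjusted p = 0.00369, adjusted p = 0.908 with an estimated correlation), with 0.03 and no call without KI-96 replicate 4. Meningeal fibroblast markers were positive in 10 of 14 (median 0.42, adjusted p = 0.00316, adjusted p = 0.617 with an estimated correlation), with 0.27 and no call without KI-96 replicate 4 and 0.24 without KI-96 replicate 2.

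Excitatory postsynaptic genes were positive in 15 of 21 in KI-96 (median 0.10, adjusted p = 0.00706, adjusted p = 0.941 with an estimated correlation). Grin2b, a subunit of the NMDA receptor, had 0.43 (SE 0.19). That call ended without KI-96 replicate 3 (0.07), and the median was 0.06 without WT replicate 6, 0.20 without WT replicate 3 and 0.22 without KI-96 replicate 4. Respiratory chain genes were negative in 24 of 32 (median -0.11, adjusted p = 0.0366, adjusted p = 0.995 with an estimated correlation), and without KI-96 replicate 3 the median turned to 0.04. Without that library camera called respiratory chain genes higher in KI-96 (adjusted p = 0.00507). Their call ended without WT replicates 1, 2, 3 or 7 (medians of -0.09 to -0.11), and the median was -0.19 without KI-96 replicate 4. Immediate early genes were negative in 20 of 24 (median -0.22, adjusted p = 0.0366, adjusted p = 0.941 with an estimated correlation). That call ended without any 1 of WT replicates 1, 2, 5 or 6 or KI-96 replicates 1, 3 or 4 (medians of -0.16 to -0.35), and the median was -0.36 without KI-96 replicate 2.

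Other settings moved several of these lists in KI-96 against WT. With the Y-linked covariate choroid plexus markers lost their call (median -0.14) and ependymal markers kept theirs (-0.45). The calls of respiratory chain (-0.04), immediate early (-0.09), interferon (0.31), excitatory postsynaptic (-0.06), thalamus (0.54) and meningeal (0.20) lists ended too. With 1 surrogate variable those of respiratory chain (-0.02), immediate early (-0.18) and excitatory postsynaptic (0.09) genes ended, and protocadherins were at 0.20. Without the 3 libraries with high cortical markers, and with the cortical marker covariate, the respiratory chain call ended (-0.10 in both), and excitatory postsynaptic genes were at 0.19 and 0.20. Without those 3 and KI-96 replicate 3 the cholesterol synthesis call ended (-0.08) and protocadherins were at 0.19. Respiratory chain genes turned to 0.06 there, and camera called them higher in KI-96 (adjusted p = 0.00372).

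The remaining lists did not pass camera in KI-96 against WT. Their medians and adjusted p-values were -0.02 and 0.977 for interneurons, -0.10 and 0.344 for homeostatic astrocytes, 0.03 and 0.977 for reactive astrocytes, -0.00 and 0.977 for homeostatic microglia, and -0.05 and 0.842 for activated microglia. They were -0.08 and 0.149 for myelin, 0.19 and 0.162 for oligodendrocyte precursors, -0.16 and 0.210 for cytosolic chaperones, -0.01 and 0.895 for endoplasmic reticulum stress, and 0.01 and 0.954 for autophagy and lysosome. They were -0.02 and 0.991 for the proteasome, -0.10 and 0.457 for the p53 response, 0.06 and 0.842 for mismatch repair and repeat instability, and -0.02 and 0.954 for nucleocytoplasmic transport. They were 0.17 and 0.388 for silenced developmental regulators, -0.70 and 0.954 for cortical neurons, -0.05 and 0.991 for septum and hypothalamus, -0.20 and 0.954 for blood, and 0.16 and 0.116 for endothelium and pericytes. Dlx1 fell adjusted over the list alone (-0.52, SE 0.16), with 0 members called over all genes.

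To compare the mutant striata directly, KI-96 was set against E1, a contrast in which all 8 libraries lacked Y-linked expression. Coq10b had the smallest p, at 12.2 ± 1.37 CPM (SD, n = 4) in KI-96 and 21.5 ± 2.29 (n = 4) in E1 (log2 fold change -0.81, SE 0.12, adjusted p = 0.0544). Dlx1, a homeobox gene of forebrain inhibitory neurons (chromosome 2, 71528113 to 71533981), had 17.1 ± 2.15 CPM (n = 4) in KI-96 and 36.2 ± 11.5 (n = 4) in E1 (-1.08, SE 0.18, adjusted p = 0.108). Arc (chromosome 15, 74669083 to 74672570) had 95.7 ± 32.1 CPM (n = 4) and 236 ± 34.6 (n = 4), with a log2 fold change of -1.30 (SE 0.27, adjusted p = 0.178). EdgeR called 0 of 18278 genes, with 1433 genes higher and 1174 lower in KI-96 at an unadjusted p under 0.05. DESeq2 called 202 genes and limma-voom 0. The count rose to 190 genes without E1 replicate 4 and to 128 without KI-96 replicate 4. It was 1 without WT replicate 1 (Coq10b) or KI-96 replicate 3 (the liver gene Alb).

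The other genes with the smallest p-values in KI-96 against E1 had an adjusted p of 0.178. Shc3, a neuronal signalling adaptor (chromosome 13, 51431041 to 51569419), had a log2 fold change of 0.73 (SE 0.14). Polr2a, the large subunit of RNA polymerase II (chromosome 11, 69733997 to 69758637), had 0.54 (SE 0.11), and the carrier gene Slc35e4 (chromosome 11, 3907021 to 3914664) had 0.49 (SE 0.10). Fzd10, a Wnt receptor (chromosome 5, 128600844 to 128604093), had 2.39 (SE 0.45) at low levels, 2.92 ± 1.90 CPM (SD, n = 4) in KI-96 and 0.563 ± 0.233 (n = 4) in E1. Pcdhgb1, a protocadherin that shares exons with its cluster and is uncertain (chromosome 18, 37680233 to 37841870), had 0.94 (SE 0.20). Plk5, a polo-like kinase (chromosome 10, 80356459 to 80365489), had -1.14 (SE 0.22). Tcim (chromosome 8, 24437180 to 24438984) had 1 to 4 counts per library in KI-96 and 9 to 18 in E1.

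Immediate early genes were lower in KI-96 than in E1. All 24 had negative fold changes (median -0.92), and adjusted over the list alone 19 fell, while 0 did over all genes. Among them were Dusp6 (-0.96, SE 0.20), the MAP kinase phosphatase Dusp1 (-0.89, SE 0.19), and the transcription factors Junb (-1.03, SE 0.23) and Nr4a1 (-1.16, SE 0.30). The list mean was 4.39 to 4.93 in the 4 KI-96 libraries, below all 4 E1 libraries (exact permutation p = 0.0286, the smallest 70 splits can give). Camera gave an adjusted p of 1.0e-18, and the adjusted p = 0.132 with an estimated correlation. The call held on leaving out each library in turn.

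Genes of the ventricle lining, of sterol synthesis and of neighbouring tissue also passed camera in KI-96 against E1, though single libraries of the groups overlapped. Exact permutation p-values of the list means were 0.0857 for ependymal, 0.200 for cholesterol synthesis and 0.200 for thalamus markers. All 13 ependymal and cilia markers were negative (median -1.002, adjusted p = 9.6e-08, adjusted p = 0.493 with an estimated correlation), and adjusted over the list alone 8 fell, among them Ccdc153 (-1.32, SE 0.43) and Dynlrb2, a dynein subunit (-1.53, SE 0.55). Cholesterol synthesis genes were negative in 22 of 24 (median -0.16, adjusted p = 0.000391, adjusted p = 0.631 with an estimated correlation), with -0.09 without KI-96 replicate 3. Adjusted over the list alone 5 of them fell, including Idi1 (-0.59, SE 0.15) and Msmo1 (-0.53, SE 0.13). Clustered protocadherins were positive in 20 of 21 (median 0.38, adjusted p = 3.19e-05, adjusted p = 0.493 with an estimated correlation). Markers of thalamus, pallidum and habenula were positive in 12 of 13 (median 0.78, adjusted p = 8.5e-05, adjusted p = 0.493 with an estimated correlation). Adjusted over the list alone 5 of these rose, among them the transcription factors Tcf7l2 (1.38, SE 0.42) and Rora (0.73, SE 0.16), and the call ended without KI-96 replicate 4 (0.44). Over all genes 0 members of these lists passed.

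Of 22 listed silenced developmental regulators, 10 had enough counts to be tested, so these 10 were not silent here. They did not pass camera as a list in KI-96 against E1 (median 0.30, adjusted p = 0.672). Of its members 4 changed adjusted over the list alone, and 0 over all genes: Dlx1 and its cluster neighbour Dlx2 (-0.68, SE 0.24) fell, and Sfmbt2 (1.00, SE 0.28) and Foxd1 (1.11, SE 0.35) rose. Blood markers were negative in 6 of 7 (median -1.02, adjusted p = 0.00620, adjusted p = 0.493 with an estimated correlation), with 5 lower adjusted over the list alone, 0 over all genes, and -0.66 and no call without E1 replicate 2. Myelin genes were positive in 19 of 23 (median 0.24, adjusted p = 0.00158, adjusted p = 0.712 with an estimated correlation). Their call ended without E1 replicate 2 (0.11), E1 replicate 3 (0.07) or KI-96 replicate 4 (0.09), and the median was 0.50 without E1 replicate 4. Oligodendrocyte precursor markers were positive in 10 of 11 (median 0.21, adjusted p = 0.00862, adjusted p = 0.493 with an estimated correlation). The precursor genes Pdgfra (0.48, SE 0.15) and Cspg4 (0.51, SE 0.14) rose adjusted over the list alone, and over all genes 0 members did. That call ended without E1 replicate 2 (0.12) or KI-96 replicate 4 (0.10), and the median was 0.37 without E1 replicate 4 and 0.33 without KI-96 replicate 3.

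Another 8 lists passed camera in KI-96 against E1, and each lost its call with an estimated correlation and on leaving out at least 1 library. Cortical neuron markers were negative in 13 of 15 (median -1.72, adjusted p = 0.0297, adjusted p = 0.712 with an estimated correlation), and the call ended without any 1 of E1 replicates 2 or 3 or KI-96 replicates 1, 2 or 4 (medians of -1.13 to -2.25). Interferon response genes were negative in 24 of 25 (median -0.67, adjusted p = 0.0152, adjusted p = 0.747 with an estimated correlation), turned to 0.19 without E1 replicate 1 and lost the call without KI-96 replicate 1 (-0.54) or 2 (-0.48). Respiratory chain genes (median -0.14, adjusted p = 0.00352, adjusted p = 0.712 with an estimated correlation) turned to 0.03 without KI-96 replicate 3 and were at -0.25 without KI-96 replicate 4. Proteasome genes (median -0.16, adjusted p = 0.00850, adjusted p = 0.712 with an estimated correlation) were at -0.04 without KI-96 replicate 3, lost the call also without E1 replicate 2 (-0.15) and were at -0.23 without KI-96 replicate 4. The subunits Psmc6 (-0.32, SE 0.09) and Psma4 (-0.51, SE 0.15) fell adjusted over the list alone, and over all genes 0 did. Chaperone genes (median -0.22, adjusted p = 0.0152, adjusted p = 0.712 with an estimated correlation) lost the call without KI-96 replicate 3 (-0.08) or E1 replicate 3 (-0.17). Genes of the p53 response (median -0.22, adjusted p = 0.00831, adjusted p = 0.493 with an estimated correlation) lost it without KI-96 replicate 3 (-0.22), and the stress-response gene Sesn1 fell adjusted over the list alone (-0.44, SE 0.11) and 0 did over all genes. Endoplasmic reticulum stress genes (median -0.20, adjusted p = 0.0472, adjusted p = 0.712 with an estimated correlation) lost it without any 1 of WT replicates 3 or 5, E1 replicates 1 or 3 or KI-96 replicates 1, 3 or 4 (medians of -0.06 to -0.22). Meningeal fibroblast markers (median 0.21, adjusted p = 0.0409, adjusted p = 0.493 with an estimated correlation) lost it without any 1 of E1 replicates 1, 2 or 3 or KI-96 replicates 2 or 4 (medians of 0.17 to 0.25), with 0.50 without E1 replicate 4 and 0.32 without KI-96 replicate 3.

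Other settings moved several of these lists in KI-96 against E1. Without the 3 libraries with high cortical markers myelin genes turned to -0.15 and cortical markers to 0.45. Interferon genes were at -1.25, with 2 E1 libraries left, among them E1 replicate 1. The calls of precursor (0.02), cholesterol synthesis (-0.08), chaperone (-0.15), endoplasmic reticulum stress (-0.03), proteasome (-0.13), p53 response (-0.22) and meningeal (0.16) lists ended. Without those 3 and KI-96 replicate 3 the calls of cholesterol synthesis (0.02), proteasome (-0.00) and p53 response (-0.14) genes ended, as did those of respiratory chain (0.02), chaperone (-0.01), endoplasmic reticulum stress (0.03) and myelin (-0.03) genes. With the cortical marker covariate those of myelin (0.09), precursor (0.15), cholesterol synthesis (-0.06), endoplasmic reticulum stress (-0.12), proteasome (-0.14), cortical (0.05) and meningeal (0.20) lists ended. With 1 surrogate variable the chaperone (-0.14), endoplasmic reticulum stress (-0.12), respiratory chain (-0.02) and proteasome (-0.08) calls ended, and myelin (0.40), precursor (0.31) and meningeal (0.32) lists were further from 0.

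The lists that did not pass camera in KI-96 against E1 had medians and adjusted p-values of -0.06 and 0.198 for projection neurons, -0.11 and 0.945 for the direct pathway, -0.02 and 0.940 for the indirect pathway, 0.34 and 0.117 for interneurons, and 0.07 and 0.113 for homeostatic astrocytes. They were -0.14 and 0.149 for reactive astrocytes, -0.06 and 0.758 for homeostatic microglia, -0.04 and 0.945 for activated microglia, -0.05 and 0.945 for autophagy and lysosome, and 0.14 and 0.110 for mismatch repair and repeat instability. They were -0.02 and 0.995 for nucleocytoplasmic transport, 0.05 and 0.332 for the excitatory postsynapse, 0.18 and 0.122 for septum and hypothalamus, -0.07 and 0.672 for choroid plexus, and 0.06 and 0.620 for endothelium and pericytes. Ptprm, an adhesion phosphatase of the indirect pathway list (0.36, SE 0.11), and Myh11, the smooth muscle myosin (1.35, SE 0.33), rose adjusted over the list alone, and over all genes 0 did.

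**Figure D3:**
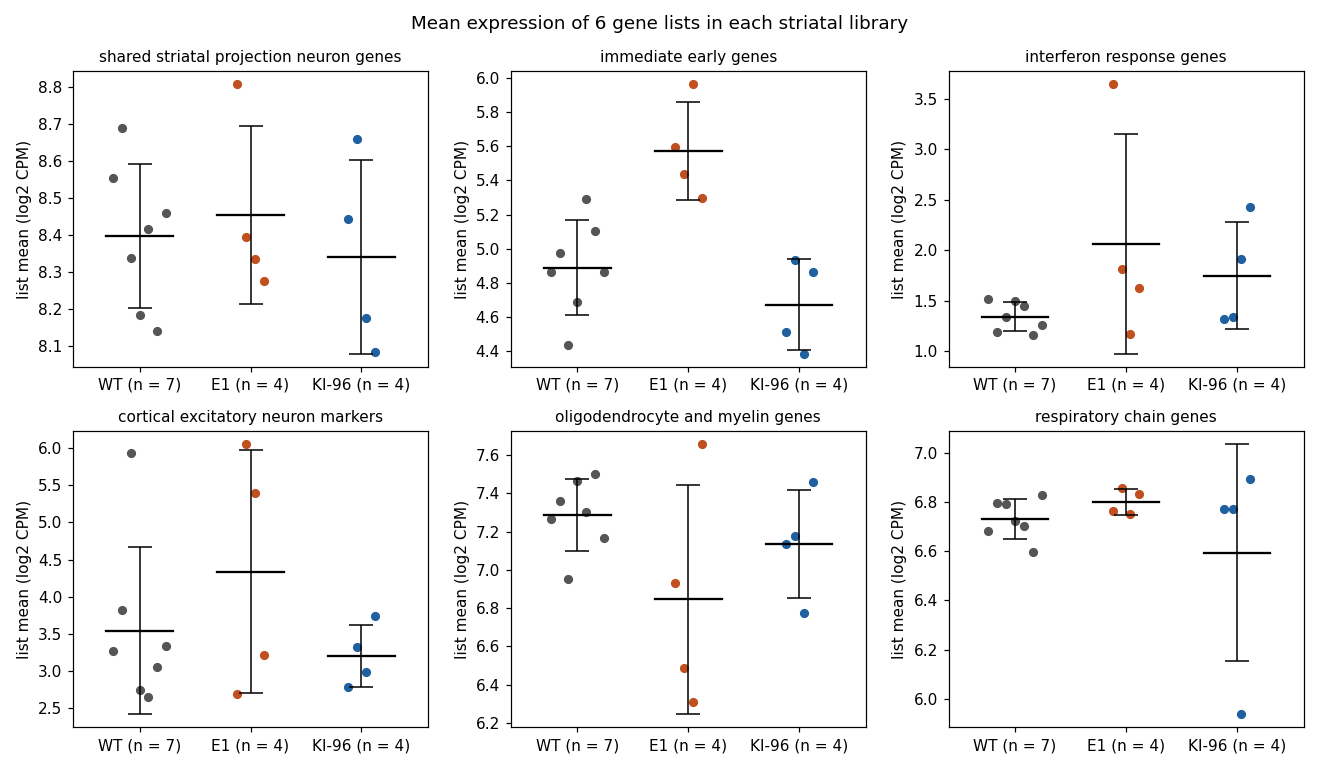
Mean log2 CPM (vertical axis) of 6 gene lists in each library (points) of WT (n = 7), E1 (n = 4) and KI-96 (n = 4), with group mean (line) and SD (bars). Immediate early genes lie between 5.29 and 5.96 in E1, 4.44 and 5.29 in WT and 4.39 and 4.93 in KI-96, and cortical markers reach 5.93 in 1 WT library and 6.05 in 1 E1 library.

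Across lists, camera with the preset correlation called 15 of 34 lists in E1 against WT (9 higher, 6 lower), 11 in KI-96 against WT (5 higher, 6 lower) and 16 in KI-96 against E1 (5 higher, 11 lower). With an estimated correlation 1, 0 and 0 were called, the 1 being the sex-linked genes. Fry called 2, 1 and 1, and the adjusted exact permutation test of list means called 0 in each, with smallest adjusted p-values of 0.103, 0.309 and 0.486.

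To ask whether E1 and KI-96 shared effects, their log2 fold changes against WT were correlated across genes, which are not independent replicates. The correlation was 0.426 over 18278 genes, and 0.356 for simulated unchanged groups against the same WT libraries. The covariance was 0.0741, against 0.0277 in the simulation. Over 17660 autosomal genes the correlation was 0.276 and the covariance 0.0380, with 0.353 and 0.0276 in the simulation. Splitting the WT libraries between the comparisons gave a correlation of 0.418 in the planned split and a median of 0.182 in 19 further splits (range 0.0687 to 0.404). Over autosomal genes the 20 splits had a median correlation of 0.00893 (range -0.103 to 0.269) and a median covariance of 0.00155. EdgeR calls shared by both comparisons numbered 0, as the 0 calls of KI-96 require. At an unadjusted p under 0.05, 81 genes were higher in both and 113 lower in both. Simulated unchanged groups against the same WT libraries shared 62 (range 47 to 78) and 54.5 (46 to 71) in the median of 20 runs. The simulated lists were smaller, with 423 and 413.5 genes higher and 439.5 and 440 lower in E1 and KI-96 in the median, against the real 674 and 1060 higher and 925 and 856 lower, so that the shared counts are not matched. The share of genes with the same sign in both was 55.1%, below the 61.7% of the simulation.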

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

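Of 192 groups of values checked for a single library far from the others of its group, 15 held one, where chance marks about 1 group in 20, or 9.6 here. None of these differences was tested further in this part.

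The gene values in WT replicate 1 stood apart for sex-linked reads and 2 other genes. Ddx3y and Kdm5d, both Y-linked, were at 0 CPM in WT replicate 1, against 54.7 to 75.3 and 38.5 to 49.7 in the other 6 WT libraries, and the sex-linked list mean was -0.63 against 4.12 to 4.45. Catspere1 on chromosome 1 was at 0.0579 CPM there and 3.80 to 10.0 in the others. The antisense gene 1700034H15Rik was at 3.65 CPM against 5.83 to 6.66.

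Markers of neighbouring tissue marked 2 further WT libraries. Cortical excitatory neuron markers had a mean log2 CPM of 5.93 in WT replicate 3 and of 2.65 to 3.82 in the other 6. Meningeal fibroblast markers were at 1.12 in WT replicate 3 against 1.44 to 1.63, and Dpysl5 was at 34.4 CPM there against 43.7 to 50.5. Choroid plexus markers were at 2.99 in WT replicate 2 and at no more than 1.93 in the other 6. In E1, Tcim was at 0.506 CPM in replicate 2 and at 0.871 to 0.945 in the other 3.

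KI-96 replicate 3 lay far below the other 3 libraries of its group for 5 gene lists. Respiratory chain genes had a mean log2 CPM of 5.94 there and of 6.77 to 6.89 in the other 3 KI-96 libraries. Proteasome genes were at 5.83 against 6.27 to 6.29, and autophagy and lysosome genes at 5.68 against 6.00 to 6.07. Homeostatic astrocyte markers were at 7.13 against 7.55 to 7.63, and activated microglia genes at 3.50 against 4.09 to 4.18. Mitochondrial genes took 3.62% of counts in KI-96 replicate 3, the lowest share of the 15 libraries, against 4.57% to 6.37% in the other 3. Whether these lists or the library as a whole differed was not tested.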

How the results depend on the processing

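Leaving out 3 libraries with high cortical markers (WT replicate 3, E1 replicates 2 and 3), KI-96 replicate 3 as the library apart on the first component or all 4, the cortical marker covariate, the autosomal and further WT splits of the overlap, the exact permutation of list means and the Y-linked covariate on lists were chosen after the data were seen. Where a value below moved, the cause was not tested, except that leaving out libraries also lowers the number of animals.

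The count of genes past the threshold for E1 against WT, 1 by edgeR, was 58 by DESeq2. By limma-voom it was 2 (Dusp5 and the X-linked Xist), and without robust estimation 3 (Dusp5 and the Y-linked Ddx3y and Kdm5d). With the replicate number as a block it was 4, the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, and Dusp5 was not called (log2 fold change 0.79). It was 0 with no filter, with only the 2 groups in the fit, with the Y-linked covariate, without the 3 libraries, without those 4 and with the cortical marker covariate, while 1599 genes had an unadjusted p under 0.05 in the edgeR model with all libraries. Leaving out 1 library gave 0 to 257, with 257 without E1 replicate 4 and 12 without WT replicate 1. Dusp5 kept its direction under each setting it was run with, DESeq2 and the fits named for counts alone not among them. It had a log2 fold change of 0.63 without the 3 libraries, 0.74 with the cortical marker covariate and 0.68 to 0.86 on leaving out 1 library. For KI-96 against WT the count of 0 (1916 unadjusted, 0 by limma-voom) became 70 by DESeq2, 1 with no filter, 1 at a mean CPM of at least 1, 6 with the block (4 of them those Y-linked genes), 1 with 1 surrogate variable, 2 without KI-96 replicate 3 and 3 without those 4 libraries. The call at a mean CPM of at least 1 was the liver gene Alb. Those without KI-96 replicate 3 were Alb and Tmem181b-ps, and without those 4 libraries the liver gene Ahsg joined them. Leaving out 1 library gave 0 to 11, with 11 without WT replicate 1 and 2 without KI-96 replicate 3 or 4. For KI-96 against E1 the count of 0 (2607 unadjusted, 0 by limma-voom) became 202 by DESeq2, 3 with no filter, 1 at a mean CPM of at least 1 and 1 without KI-96 replicate 3. Leaving out 1 library gave 0 to 190, with 190 without E1 replicate 4, 128 without KI-96 replicate 4 and 1 without WT replicate 1 or KI-96 replicate 3. The call without KI-96 replicate 3 was Alb.

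Camera calls of lists, 15, 11 and 16 in the order above, became 1, 0 and 0 with an estimated correlation, 2, 1 and 1 with fry, and 0 in each with the exact permutation of list means. With the replicate number as a block the calls of interneuron (median -0.11), reactive astrocyte (0.02), p53 response (0.12), cortical (0.46) and thalamus (-0.26) lists ended in E1 against WT, where homeostatic astrocyte markers were at -0.15 and ependymal markers at 0.64. It ended those of immediate early (-0.07) and excitatory postsynaptic (0.04) genes in KI-96 against WT, with ependymal markers at -0.44, and those of endoplasmic reticulum stress (-0.19) and interferon (-0.41) genes in KI-96 against E1. With the Y-linked covariate camera called 5 lists in KI-96 against WT, and without the 3 libraries 10 in KI-96 against E1. Both counts include lists that were not called over all libraries without a covariate. Leaving out 1 library gave 9 to 18, 8 to 14 and 10 to 21, with 9 without E1 replicate 2 and 10 without KI-96 replicate 4. The correlation of the E1 and KI-96 effects, 0.426, was 0.276 over autosomal genes and 0.182 in the median of 19 further splits of WT.

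Over the genes named by rule, 280 of the values under other settings and 449 of those with 1 library left out kept their direction and their side of the threshold, 4 and 11 no longer passed it, 7 and 34 newly passed it, and 3 and 1 changed sign. Over the called lists 261 and 553 kept both, 141 and 74 no longer passed, and 18 and 3 changed direction.

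The values below turned in sign or in the direction of their test. The value of Htt, KI-96 vs WT, 0.06, was -0.0507 with 1 surrogate variable, -0.0841 without KI-96 replicate 3, -0.0856 without those 4 libraries and up to 0.17 on leaving out 1 library. Cortical excitatory neuron markers in E1 against WT had a median of 1.00 over all libraries. They were at -0.21 without the 3 libraries, -0.21 without those 4 and -0.02 with the cortical marker covariate. In KI-96 against E1 the same markers were at 0.45, 0.39 and, with the cortical marker covariate, 0.0490. Without those 4 libraries camera called them higher in KI-96 than in E1 (adjusted p = 0.0460). With the Y-linked covariate sex-linked genes were at -0.33 in E1 and -0.34 in KI-96 against WT, cholesterol synthesis genes in KI-96 against WT at 0.0595 and excitatory postsynaptic genes at -0.0558. Medians of respiratory chain genes, KI-96 vs WT, were at -0.0198 with 1 surrogate variable, where the direction of the test turned, at 0.0624 without those 4 libraries, and at -0.19 (without KI-96 replicate 4) to 0.0408 (without KI-96 replicate 3) on leaving out 1 library. Camera called that list higher in KI-96 than in WT without those 4 libraries (adjusted p = 0.00372) and without KI-96 replicate 3 (adjusted p = 0.00507). In KI-96 against E1 medians of respiratory chain genes were at 0.0177 without those 4, and at -0.25 to 0.0267 on leaving out the same libraries. Medians of oligodendrocyte and myelin genes, KI-96 vs E1, were at -0.15 without the 3 libraries and -0.0330 without those 4, and in the same comparison without those 4 libraries cytosolic chaperone genes were at -0.0125, where the direction of the test turned, and endoplasmic reticulum stress genes at 0.0305. Medians alone changed sign for reactive astrocyte genes, E1 vs WT (-0.02 without E1 replicate 1), for oligodendrocyte and myelin genes, E1 vs WT (0.00474 without those 4), and for cholesterol synthesis genes, KI-96 vs E1 (0.0196 without those 4). In KI-96 against E1 interferon response genes ran from -0.95 without E1 replicate 3 to 0.19 without E1 replicate 1.

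Replicate numbers were not treated as pairs, since each library carries its own mouse number. After group means were removed, correlations between libraries of the same number ran from -0.103 to 0.191 (E1 and WT), -0.0691 to 0.183 (KI-96 and WT) and -0.0111 to 0.194 (KI-96 and E1). They passed 0.1 for 2, 1 and 2 of 4 pairs. Libraries of different numbers were not compared in this way, so these values cannot tell whether the numbers carry a pairing. Depth and spread limited the folds that could be seen, with a median 95% half-width of 0.35 log2 units per gene in either comparison with WT and of 0.40 in KI-96 against E1.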

Other observations

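All tests in this part except that of the further liver genes were chosen after the results were seen.

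Some genes had 2 levels whose split did not match the genotype groups, though for several the high libraries were all WT. Of 18278 genes 24 had a gap of over 2 log2 units between 2 sets of libraries, 17 of them autosomal and 12 pseudogenes. Eno1b, a copy of an enolase gene, had 815 to 854 counts in WT replicates 5 to 7 and at most 23 elsewhere. Eif3j2, a copy of a translation factor gene, had 100 to 119 counts in WT replicates 2 to 4 and at most 24 elsewhere, and the pseudogene Gm28438 had 1205 to 1606 and at most 122 with the same split. Gm8730 had 582 to 1131 counts in WT replicates 6 and 7 and at most 15 elsewhere. Atp6v0c-ps2 (868 to 2273 against at most 26) and Gm9825 (68 to 206 against at most 4), both on chromosome 6, were low in the same 6 libraries: WT replicates 1 and 4, E1 replicate 3 and KI-96 replicates 2 to 4. Vxn (2788 to 4045 against at most 511) and Ipcef1 (1122 to 1213 against at most 272) were high in WT replicate 3 and E1 replicates 2 and 3. These are the libraries with high cortical markers. Catspere1 was the 1 autosomal gene of the 24 that split the libraries like the Y-linked genes.

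In E1 replicate 1 the antiviral genes Irf7 and Ifit1 were at 12.9 and 17.6 CPM.

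Immediate early genes were higher in E1 than in WT by 0.68 log2 units in the list mean (SE 0.18, n = 4 and 7). Cortical tissue in some samples was argued against as the whole cause, since the difference was 0.71 (SE 0.19) with the cortical marker mean as a covariate, though it was 0.48 (SE 0.17, n = 2 and 6) without the 3 libraries with high cortical markers. Library size was argued against too, with 0.83 (SE 0.19) against the 4 WT libraries of similar totals. Sex was argued against for the difference from KI-96, which also lacked Y-linked reads and lay -0.90 (SE 0.20) from E1. For E1 against WT it was not settled, because an effect of the KI-96 genotype could offset one of sex. The larger exact permutation p of E1 against WT and against KI-96 was 0.0286. An effect of the E1 genotype and of how or when animals were handled before death cannot be told apart, because the labels do not state the handling, and it could differ between groups.

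Htt was lower in E1 by 20.9% (95% interval 7.41 to 32.4%). Cortical tissue was argued against as the whole cause, since the log2 fold change was -0.33 (SE 0.11) with the cortical marker covariate. Sex was not settled for E1 against WT. KI-96, which also lacked Y-linked reads, was higher than E1 by 0.25 (SE 0.09) without KI-96 replicate 3, but the KI-96 genotype could itself shift Htt. A loss of reads from the first exon, where the CAG repeat lies, cannot be told apart from lower expression or stability of the Htt transcript, because reads per exon were not measured. That exon holds 2.77% of the longest transcript by length, and Htt was lower by 7.41% at the end of the interval nearest 0.

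Transcripts of liver were read in KI-96 libraries. Alb, which encodes serum albumin, had 467 counts in KI-96 replicate 4, 124 in replicate 1, 26 in replicate 2, 2 in replicate 3 and 0 to 2 in WT and E1 libraries. RNA from liver is consistent with a test written before its result: 19 of 22 further liver genes had their highest CPM in KI-96 replicate 4, where 1.47 are expected by chance for 1 library. These 22 genes, Alb not among them, took 33.9 CPM in KI-96 replicate 4, 9.24 in replicate 1 and 2.78 to 6.28 in the other 13 libraries. Alb alone took 19.4 CPM in KI-96 replicate 4. Expression in KI-96 striatum cannot be told apart from it for replicates 1 and 2. A rise in every KI-96 striatum would not leave replicate 3 with no more Alb counts than the highest WT or E1 library, but 1 library does not decide it.

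The libraries were also split into other groups of the same sizes, and the counts of splits below include the real one. For E1 against WT 13 of 100 splits gave at least the 1 gene of the real split, with up to 263 in another, so chance cannot be excluded for that count. The split with 263 set WT replicates 3 and 7 and E1 replicates 2 and 3 apart, which points to a structure of the samples and holds the 3 libraries with high cortical markers. For lists 14 of 100 splits gave at least the real 15, with up to 18. For KI-96 against WT 59 of 100 splits gave at least the real 11 lists, with up to 21. For KI-96 against E1 5 of 35 gave at least the real 16 lists, with up to 20. Chance cannot be excluded for any of these 3 counts of lists. At an unadjusted p under 0.05, 7 of 100 splits gave at least the real 1599 genes for E1 against WT (up to 2189). For KI-96 it was 6 of 100 for 1916 genes against WT (up to 2447) and 3 of 35 for 2607 against E1 (up to 3449). Chance cannot be excluded for these counts either. The split with 2189 set WT replicates 4 to 7 apart from the other WT libraries and all E1 libraries. It points to a structure within the WT group, which both comparisons with WT share, and its nature was not tested. No setting left out WT replicates 5 to 7 together. The edgeR counts of 0 genes in KI-96 against WT (1916 unadjusted, 70 by DESeq2, 0 by limma-voom) and against E1 (2607 unadjusted, 202 by DESeq2, 0 by limma-voom) are reached by any split, so that 100 of 100 and 35 of 35 splits say nothing about chance. The highest counts in other splits were 10 and 40. The 40 came with E1 replicates 1 to 3 and KI-96 replicate 3 against the rest, which points to a structure of the samples whose nature was not tested.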
